A study of Homo sapiens with 8 samples.

How the data were processed

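Gene expression was measured on 8 Agilent 4x44K 2-colour arrays, 4 per cell line, in OCILY10 and TMD8, established lines of activated B-cell-like (ABC) diffuse large B-cell lymphoma. Each line was treated with 10 µM lenalidomide, an immunomodulatory drug that binds the ubiquitin ligase receptor cereblon, and 1 array was hybridised at each of 3, 6, 24 and 48 h. On every array the Cy3 channel held RNA of the same line given the solvent DMSO and the Cy5 channel held RNA of the lenalidomide-treated cells. The labels give total RNA extracted with Trizol and 1 µg of RNA labelled per sample. Whether each DMSO culture was matched to its time point is not given in the sources used here. No array had the dyes swapped, so a gene-specific dye effect is not separated from the drug effect in any ratio tested against 0. Such an effect cancels in the difference between late and early times and in the difference between the lines.

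The deposited scanner files hold the mean spot signal and the median local background of each channel as intensity, and per the file headers they were read with Agilent Feature Extraction 10.1.1.1 under protocol GE2-v5_10_Apr08. The deposited processed signals are also in units of intensity and were background subtracted, detrended and dye normalised by linear and LOWESS fits, per the file headers. The deposited value table was found to hold the log10 of processed Cy5 over processed Cy3 signal, within 0.0005 of the value computed from the processed signals, with positive values meaning more RNA in treated cells. Its column medians lay between -0.065 and -0.015 on the log10 scale, so it had not been centred. Each array held 43376 gene spots and 1639 control spots. Of the gene spots, 41.4% to 62.8% were well above background in Cy3 and 56.5% to 73.8% in Cy5, with both highest values on the TMD8 3 h array. For arrays, the number of arrays limits the precision.

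The scanner intensities were read in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50, log2 ratios of Cy5 over Cy3 were normalised within each array by loess, and no scaling between arrays was applied. In total 165 spots marked as non-uniform were left out. Probes were kept if they were well above background in either channel on at least 2 of the 8 arrays, which left 29740 of 41000 probes. The probe of highest mean brightness stood for each gene, and 22165 genes were tested, of which 14330 had a reference symbol. Symbols were brought up to date by matching RefSeq accessions to a reference table. In that step 27610 probes matched, and 13390 kept the name or identifier in the file. Named genes without a value on at least 6 arrays were passed over.

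A linear model was fitted to each gene with limma (lmFit and eBayes), with p-values adjusted by the Benjamini-Hochberg method over all genes tested and a threshold of 0.05 on the adjusted p. Early means the 3 and 6 h arrays and late means the 24 and 48 h arrays, with 4 arrays each. The late mean and the early mean were each tested against 0, then the late minus early difference. Each time was tested against 0 with 1 array per line, and so was TMD8 minus OCILY10 at the late times. All 8 arrays shared one estimate of the spread, with 6 residual degrees of freedom in the fit by phase and 4 in the fits by time and by line. The repeated observations are thus different lines and different times, not repeats of one condition, and the p-values measure agreement across them. Whether the spread of the control cells enters a ratio tested against 0 depends on whether each array had its own DMSO culture. The sources used here do not say this. All p-values from these models are two-sided.

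Lists of genes were compared with all other genes by camera in limma with a preset correlation between genes of 0.01, adjusted over the 25 lists within each comparison. Camera with an estimated correlation was run beside it, and so was fry, which asks whether a list changed at all. The 25 lists were interferon-stimulated genes, interferon ligands and receptors, NF-κB targets, B-cell receptor and MYD88 signalling, ABC subtype, germinal-centre (GCB) subtype, plasma cell and secretory genes, B-cell identity, cereblon and its substrates, cell cycle, MYC and ribosome biogenesis, apoptosis, p53 targets, MHC class I, MHC class II, STAT3 and cytokine genes, cholesterol synthesis, glycolysis and hypoxia, amino acid stress (ATF4), heat shock, immediate early genes, T and NK cell markers, myeloid markers, stromal and epithelial markers, and housekeeping genes. Of the interferon-stimulated list, 1 gene was also in the apoptosis list, and no other list shared a gene with it.

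The comparisons, lists, named-gene rule and most alternatives were chosen before the data were examined. Named genes were those past the threshold with the largest changes. For late these were the 15 largest rises and 15 largest falls with the same sign on all 4 late arrays, and for early the 5 largest of each direction with the same sign on all 4 early arrays. They were the 10 largest of each direction for late minus early and for the line difference, and the 3 largest of each direction for each time. Up to 4 members of each list per direction and comparison were added, and so were 16 genes of ABC lymphoma, interferon signalling and cereblon biology whatever their values. Where no gene passed, the 3 of smallest p in each direction were named. Clone names and identifiers without a symbol were passed over. The values of 3 of the named genes are not reported here.

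The alternatives were Agilent's processed signals, the value table, a normexp offset of 0, median centring, scaling between arrays, no filter and a strict filter on dim probes (both channels on all 8 arrays), non-uniform spots kept, the mean of all probes of a gene, and the cell line or the slide as a block. Median centring took the place of loess and subtracted 1 constant per array, so any dye trend with brightness stayed in its values. Further alternatives were the arrays of a comparison alone, each line alone, eBayes with trend and robust settings, a minimum of 1.5-fold, and each array left out in turn. The 3 and 6 h arrays as baseline and median centring over the tested genes were added after seeing the data. Slide 1 held all 4 OCILY10 arrays, slide 2 the TMD8 24 and 48 h arrays, and slide 3 the TMD8 3 and 6 h arrays, which were scanned on a second day. The slide entered as a random block (duplicateCorrelation with statmod 1.5.0; consensus correlation 0.00277 by phase and 0.0537 by time), except for late minus early, where it was a fixed term.

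The fit was tested on simulated data made of independent normal noise with each gene's own residual spread, to which known changes in both directions were added at the late times. In the late comparison it recovered 60 of 67 genes changed by 0.5 on the log2 scale, 65 of 67 changed by 1 and 66 of 66 changed by 2, with 9 false calls among 216. For late minus early it recovered 44 of 67, 63 of 67 and 66 of 66, with 4 false calls among 187. An addition of 0.5 to the housekeeping list made it the 1 list called in each of these comparisons, and no gene or list was called in the early comparison, to which nothing had been added. The simulated noise held no dye effect, no component shared by an array, line or slide, and no correlation between genes. These counts thus do not show how the fit performs where such effects are present. Figures were drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.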

Results

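RNA from 2 ABC lymphoma cell lines, OCILY10 and TMD8, was compared with RNA of the same line in DMSO after 3, 6, 24 and 48 h in 10 µM lenalidomide. Each line gave 4 arrays, 1 per time, so no single condition was repeated. Values are log2 ratios of treated over DMSO-treated cells, given as the mean ± SD over arrays or with a standard error (SE) from the limma fit. Of 22165 genes tested, 14330 carried a reference symbol. The series title names synthetic lethality as a route to therapy of ABC lymphoma. The time course shows which transcripts differed between treated and DMSO-treated cells, and at which times. Without swapped dyes, a gene-specific dye effect is not separated from the drug effect in these ratios. Such a dye effect cancels only in differences between late and early times or between the lines.

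At 24 and 48 h the largest rises were in interferon-stimulated genes. Of 53 interferon-stimulated genes measured from a list of 55, 43 rose, none fell and 10 did not pass the test, and 49 rose when adjusted over the list alone. IFI44L and IFI27, interferon-induced transcripts, rose by 2.76 ± 1.55 (SD, n = 4; adjusted p = 0.0121) and 2.74 ± 1.84 (adjusted p = 0.02) on the log2 scale. IFIT1, which binds foreign RNA lacking cap methylation, rose by 2.58 ± 1.60. OAS3, an activator of antiviral RNA decay, rose by 1.33 ± 0.52 (adjusted p = 0.00506), and IFITM1, a barrier to viral entry, rose by 1.28 ± 0.47 (adjusted p = 0.00384), each on all 4 late arrays. The interferon-inducible genes IFI44, XAF1, IFIT2, IFIT3 and DDX60 rose by 1.17 to 2.19. IRF7, which drives interferon transcription, rose by 0.76 ± 0.68 (adjusted p = 0.0464), although its value on the TMD8 24 h array was -0.24. The mean over the list was 0.92 ± 0.55 over the 4 late arrays (adjusted p = 1.4e-23 by camera), with adjusted p = 0.446 with an estimated correlation and a range of 3.9e-43 to 0.446 over the alternatives. By array it was 1.17 and 1.31 in OCILY10 and 0.10 and 1.11 in TMD8 at 24 and 48 h, and without the TMD8 24 h array the late mean was 1.19 ± 0.10 (n = 3), with 49 members past the threshold.

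**Figure D1:**
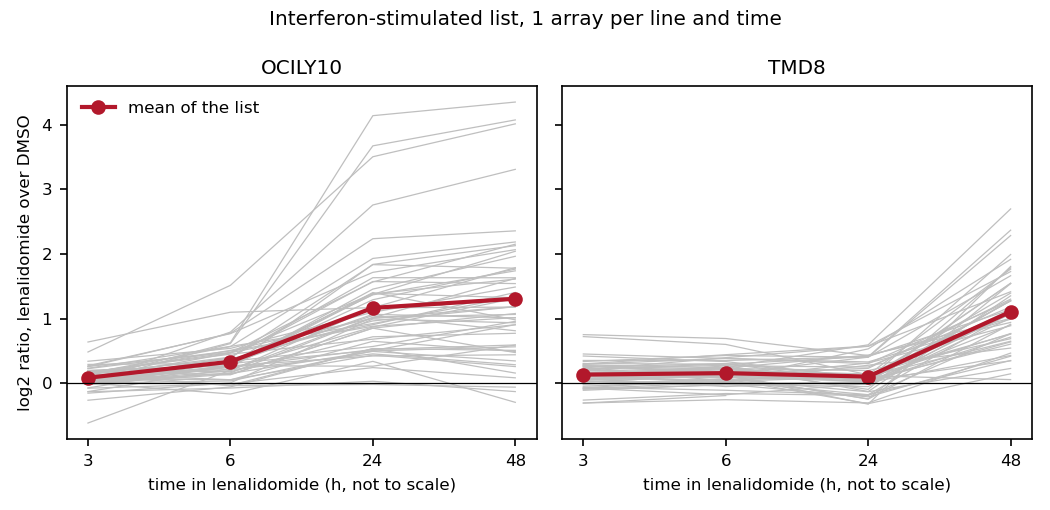
Log2 ratio of lenalidomide over DMSO for each measured interferon-stimulated gene (grey lines) and their mean (red) against time in hours, with OCILY10 and TMD8 in separate panels and 1 array per point. The list mean reached 1.17 at 24 h and 1.31 at 48 h in OCILY10, and in TMD8 it was 0.10 at 24 h and 1.11 at 48 h.

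Upstream of that response, IFNB1, which encodes interferon beta, had a fitted log2 ratio of 0.93 at the late times (SE 0.21, adjusted p = 0.0304, higher on 8 of 8 arrays). Its DMSO signal was not well above background on any late array, so the size of the rise is uncertain. The value also depended on the setting, with fitted log2 values of 0.58 under scaling between arrays and 0.44 in TMD8 alone. Of 14 measured interferon ligands and receptors, 2 rose and 2 fell, and the list as a whole did not pass (adjusted p = 0.471). IFNLR1, a subunit of the lambda interferon receptor, rose by 0.37 (another probe stood at -0.066), while JAK1, a kinase shared by interferon receptors, fell by 0.34 (SE 0.045, adjusted p = 0.00694). IFNGR2, the signalling chain of the interferon gamma receptor, fell by 0.24, but its value was 0.083 under median centring. Of 35 measured NF-κB targets, 8 rose and 1 fell (11 and 2 when adjusted over the list alone), with a list mean of 0.17 ± 0.063 (adjusted p = 0.023), adjusted p = 0.446 with an estimated correlation and a range of 1.4e-05 to 0.446 over the alternatives. That call was also lost without the TMD8 24 h array, where the mean was 0.14 (adjusted p = 0.15), without OCILY10 24 h (adjusted p = 0.0668) and under scaling between arrays (adjusted p = 0.0833). The cytokine gene IL6 rose by 0.72 ± 0.079 (adjusted p = 0.000874, higher on 8 of 8 arrays), with DMSO signal well above background on 2 of the 4 late arrays. The chemokine gene CCL4 rose by 1.17 ± 0.46, the superoxide dismutase gene SOD2 by 0.50 (another probe stood at 0.0043) and TNFAIP2 by 0.46. RELB, an NF-κB subunit, fell by 0.26 but stood at 0.31 under median centring.

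Of 30 measured apoptosis genes, 7 rose and none fell (8 and 0 when adjusted over the list alone), though the list did not pass as a whole (adjusted p = 0.0834). CASP1, the inflammatory caspase, rose by 0.90 ± 0.40 (adjusted p = 0.0121). TNFSF10, which encodes the death ligand TRAIL and is also in the interferon list, rose by 0.66, and TNFRSF10B, a TRAIL receptor, rose by 0.44. BCL2, which blocks apoptosis, rose by 0.41 (SE 0.092, adjusted p = 0.0312), while another probe stood at 0.059. Among 22 p53 targets, MDM2, the ligase that degrades p53, rose by 0.23, 1 further member rose and 1 fell. The member that fell was BTG2, by 0.29, with a value of 0.18 under median centring, and the list did not pass (adjusted p = 0.471).

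Regulators of the ABC state gave mixed results. SPIB, an ETS factor essential in ABC lymphoma, fell by 0.42 (SE 0.071, adjusted p = 0.0145, lower on 8 of 8 arrays). Yet its value was 0.20 under median centring, which leaves in any dye trend with brightness, and adjusted p ranged from 0.00916 to 0.257 over the alternatives. Its partner IRF4, the plasma cell and ABC lymphoma factor, stood at -0.16 (adjusted p = 0.118, lower on 6 of 8 arrays) and at 0.25 under median centring. MYD88, the Toll-like receptor adaptor, stood at 0.33 (adjusted p = 0.119), and the IRF4 target PRDM1 at -0.11 (adjusted p = 0.237). None of 25 B-cell receptor and MYD88 signalling genes passed, over all genes or when adjusted over the list alone, and the list mean was 0.0094 (adjusted p = 0.94). Of 25 ABC subtype genes, 5 rose and 4 fell (6 and 8 when adjusted over the list alone). The cyclin gene CCND2 and the AP-1 factor gene BATF both rose by 0.36, and the falls included IL16 by 0.39 and the ion channel gene P2RX5 by 0.44. RAB29 fell by 0.27 and stood at 0.051 under median centring.

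**Figure D2:**
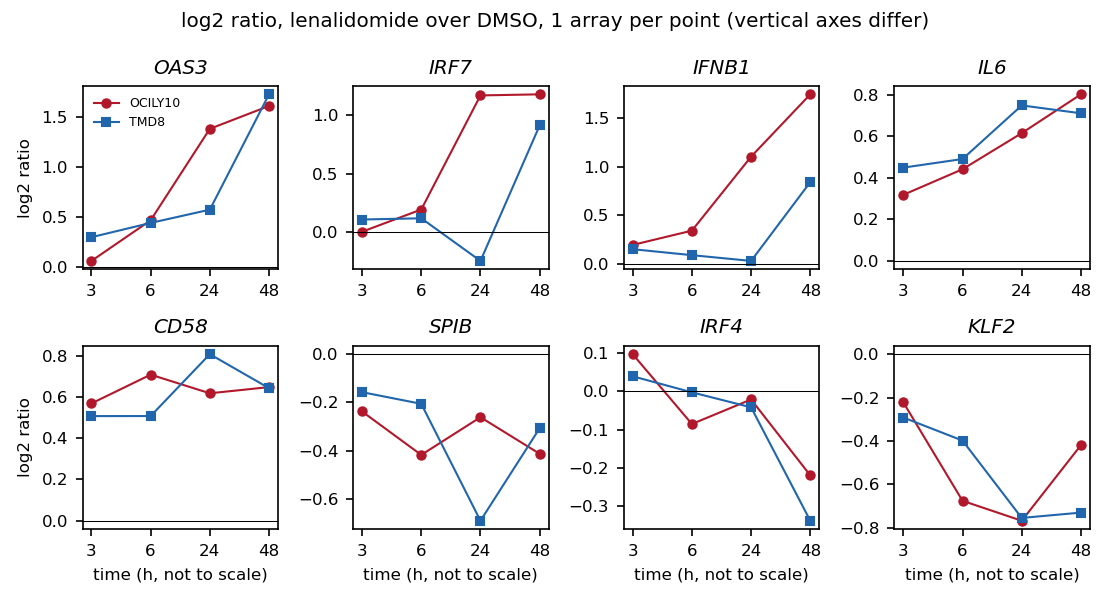
Log2 ratio of lenalidomide over DMSO against time in hours for 8 genes in OCILY10 (circles) and TMD8 (squares), 1 array per point and vertical axes that differ between panels. IL6 and CD58 lay above 0 and KLF2 and SPIB below 0 on all 8 arrays, although SPIB stood at 0.20 at the late times under median centring. The same sign on all 8 arrays can also come from a gene-specific dye effect.

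Of 20 B-cell identity genes, none rose and 4 fell over all genes (3 and 5 when adjusted over the list alone). These were the E-protein gene TCF3 by 0.43, the inhibitory receptor gene CD22 by 0.33, the CD20 gene MS4A1 by 0.32 and CD72 by 0.17, and median centring turned TCF3 to 0.13, MS4A1 to 0.045 and CD72 to 0.13. Among the named genes SPIC, an ETS factor related to SPIB, fell most, by 1.06 ± 0.63 (adjusted p = 0.0163). KLF2, a factor of B-cell quiescence and homing, fell by 0.67 ± 0.17 (adjusted p = 0.00506, lower on 8 of 8 arrays), but its value was -0.22 under median centring and -0.12 by another probe. Further falls were REEP2, which shapes the endoplasmic reticulum, by 0.64 (adjusted p = 0.00346), the granzyme inhibitor gene SERPINB9 by 0.59 (another probe stood at 0.044), the calcium-binding protein gene S100A4 by 0.56 and the hormone-sensitive lipase gene LIPE by 0.52. PTOV1, SLC12A4, BCDIN3D, SULF2, UBE2M, KDM7A and SH3TC1 fell by 0.51 to 0.58, and ADAM8 fell by 0.51 but stood at 0.018 under median centring. Outside the lists the rises included FMOD, which encodes the matrix protein fibromodulin, at a fitted log2 of 1.61 (1.08 under scaling between arrays and 0.59 in TMD8 alone). The DMSO signal of FMOD was not well above background on any late array, so the size of its rise is uncertain. PLA1A and C1orf54 rose by 1.23 and 1.18.

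Among the cereblon machinery and its substrates, 1 of 12 genes rose and none fell (2 and 0 when adjusted over the list alone), with a list mean of 0.12 (adjusted p = 0.135). The gene that rose was CUL4B, a scaffold of cullin ligases, by 0.33. CRBN, the drug's receptor, stood at 0.033 (adjusted p = 0.785), and the genes of the drug-induced degradation targets IKZF1 and IKZF3 stood at 0.35 (adjusted p = 0.139) and 0.041 (adjusted p = 0.634). MYC stood at 0.011 (adjusted p = 0.94), and of 25 MYC and ribosome biogenesis genes 2 rose and 1 fell, as they did when adjusted over the list alone. These were GNL3 by 0.30 and NPM1 by 0.24, both nucleolar, and LDHA, which fell by 0.36. NPM1 stood at -0.043 with the mean of its probes, and LDHA at 0.25 under median centring and at 0.097 by another probe. The 40 cell cycle genes had a mean of -0.062 ± 0.098 (adjusted p = 0.00701) with 1 rise and 1 fall, also when adjusted over the list alone. The call was lost at adjusted p = 0.625 with an estimated correlation, with a range of 6.9e-05 to 0.625 over the alternatives, and the mean was 0.26 under median centring. By array the mean was 0.046 and -0.14 in OCILY10 and -0.0032 and -0.15 in TMD8 at 24 and 48 h, so the lowest means lay at 48 h. The TMD8 24 h median was -0.054, with 15 of 40 genes above 0, and 24 h was not tested against 48 h. The late mean was -0.035 without OCILY10 48 h, -0.033 without TMD8 48 h (adjusted p = 0.0791) and -0.098 without OCILY10 24 h. TYMS, thymidylate synthase, rose by 0.23, and UBE2C, a mitotic ubiquitin-conjugating enzyme gene, fell by 0.17 and stood at 0.29 under median centring. The cell cycle inhibitor gene CDKN1A stood at 0.24 (adjusted p = 0.159), and the NF-κB targets TNFAIP3, NFKBIA and BCL2A1 at 0.25, 0.048 and -0.13 (adjusted p = 0.0917, 0.696 and 0.33).

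Most other lists held few calls at the late times, and none passed as a list. Antigen presentation gave 1 rise among 20 MHC class I genes, B2M by 0.32, and 2 falls among 16 MHC class II genes, with 2 rises and 1 fall and 0 rises and 2 falls when adjusted over the list alone. The class II falls were CD74, the invariant chain, by 0.34, with 0.049 under median centring, and HLA-DRB3 by 0.23. Of 17 STAT3 and cytokine genes, 2 rose and 2 fell (4 and 2 alone), among them IL6R by 0.28 and the fall of BCL3 by 0.34, which stood at 0.26 under median centring. Of 20 cholesterol synthesis genes, 1 rose and 2 fell (1 and 5 alone; list adjusted p = 0.0617), namely STARD4 by 0.20, MVK, which fell by 0.32, and SREBF2, which fell by 0.31. Under median centring MVK stood at 0.17 and SREBF2 at 0.069. Of 20 amino acid stress genes, 2 rose and 3 fell (2 and 5 alone; list adjusted p = 0.109). TRIB3 fell by 0.40, CEBPB by 0.37 and SLC3A2 by 0.31, while CHAC1 rose by 0.15 and SLC7A11 by 0.20. Median centring turned TRIB3 to 0.093, SLC3A2 to 0.098 and SLC7A11 to -0.018. Of 20 glycolysis and hypoxia genes 1 fell, as it did alone (list adjusted p = 0.0693), and of 12 heat shock genes none passed in either way (list adjusted p = 0.775). Of 16 GCB subtype genes 2 rose, LMO2 and SSBP2 by 0.49 each, and 1 fell, GCSAM by 0.34 (3 and 1 alone). Of 24 plasma cell genes 2 rose, DNAJB9 by 0.31 and SEL1L by 0.24 (2 and 0 alone), and of 18 immediate early genes KLF6 rose by 0.38 (1 and 1 alone). Of the marker lists of other cell types, 12 T and NK cell genes gave 1 fall (0 and 1 alone), CD5 by 0.43, and 10 myeloid genes gave 1 rise (2 and 0 alone), TYROBP by 0.77. The 14 stromal and epithelial genes gave 1 fall (1 and 1 alone), VIM by 0.33, with 0.26 under median centring. Among 20 housekeeping genes 2 rose (5 and 2 alone), ACTB by 0.41 (another probe stood at -0.094) and B2M by 0.32. The mean, the median and the direction of the test differed in sign for the interferon ligand and receptor, ABC subtype, plasma cell, MHC class II, T and NK cell, stromal and housekeeping lists, none of which passed.

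In all, 1877 genes passed at 24 and 48 h, 1237 higher and 640 lower (65.9% higher), with a median absolute log2 ratio of 0.27, and 36 rose and 1 fell by at least 2-fold. With the slide as a random block the count was 1856, and within slide 1, which holds the OCILY10 arrays, it was 127, against 0 in TMD8 alone (4102 at unadjusted p under 0.05, limma). The count was 0 with trend and robust eBayes (6420 at unadjusted p under 0.05) and 0 with the 4 late arrays alone (4051 at unadjusted p under 0.05), 15 with scaling between arrays (12 higher, 3 lower) and 138 with a minimum of 1.5-fold (134 higher, 4 lower). Median centring gave 3801 genes (3746 higher, 55 lower) and left the median of the tested genes at 0.23 at the late and 0.30 at the early times, so its gene and list values are given relative to these, and centring over the tested genes gave 3539 (2944 higher, 595 lower). Without OCILY10 24 h it was 2503, with only 52.1% higher (1304 higher, 1199 lower). Without other single arrays the count was 392 (OCILY10 48 h), 561 (TMD8 48 h), 814 (TMD8 3 h), 849 (TMD8 6 h), 867 (OCILY10 6 h) and 2833 (TMD8 24 h).

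**Figure D3:**
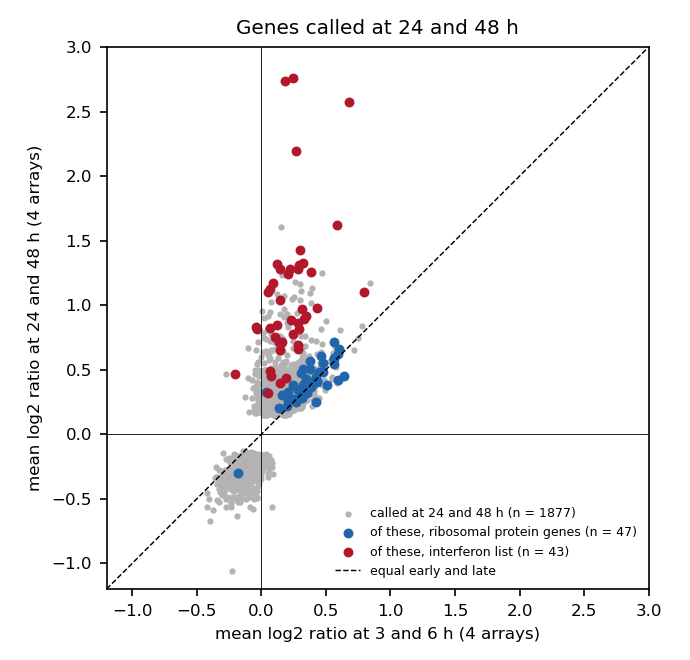
Mean log2 ratio at 24 and 48 h against that at 3 and 6 h (4 arrays each) for the 1877 genes that passed at 24 and 48 h, with ribosomal protein genes in blue (n = 47), interferon-stimulated genes in red (n = 43) and a dashed line where both are equal. The interferon genes shown mostly lay above the line, with a median early over late ratio of 0.211, and the ribosomal protein genes shown close to it, with 0.946.

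At 3 and 6 h fewer genes passed in the chosen setting and none of them changed 2-fold, although their median absolute log2 ratio was 0.34, against 0.27 at the late times. With only the arrays of each comparison, and with median centring, more genes passed early than late. The order of these counts thus depends on the setting. CD58, the adhesion ligand by which T and NK cells engage target cells, rose by 0.57 ± 0.095 (SD, n = 4; adjusted p = 0.00516 by limma, higher on 8 of 8 arrays) and stood at 0.68 ± 0.087 at the late times. A gene-specific dye effect could also give values of like size and sign at all times, and it is not separated here. Of 35 NF-κB targets, 3 rose and none fell (8 and 0 when adjusted over the list alone): IL6 by 0.43 (adjusted p = 0.00867), the cytokine gene IL10 by 0.39 (adjusted p = 0.0463) and the adhesion gene ICAM1 by 0.24 (adjusted p = 0.0398). The list mean was 0.15 ± 0.041 (adjusted p = 0.00151), with adjusted p = 0.293 with an estimated correlation and a range of 1.5e-05 to 0.293 over the alternatives. None of the 53 interferon-stimulated genes passed, over all genes or over the list alone, while their mean of 0.18 ± 0.11 passed as a list (adjusted p = 0.023). That call was lost with an estimated correlation (adjusted p = 0.97, range 2.4e-06 to 0.97 over the alternatives) and without the OCILY10 6 h array, where the mean was 0.13 (adjusted p = 0.424). It was also lost by fry (adjusted p = 0.744), with the strict filter (0.0596), with non-uniform spots kept (0.0565) and without OCILY10 24 h (0.0537) or TMD8 6 h (0.0534). The translation genes RPS27, RPL18, RPL28 and EEF1A1 rose by 0.59 to 0.64, and stood at 0.62, 0.45, 0.42 and 0.30 at the late times. Their lowest early values over the alternatives were 0.35, 0.40, 0.32 and 0.13, and other probes of RPL28 and EEF1A1 stood at -0.021 and -0.18 at the late times.

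The falls at 3 and 6 h were TNRC6B, a partner of Argonaute in microRNA silencing, by 0.45 ± 0.064 (adjusted p = 0.0463), REPIN1 by 0.42, TMBIM6 by 0.33, TERT, the catalytic subunit gene of telomerase, by 0.32 and TXNL4A by 0.31. Under median centring the last 4 stood at 0.25, 0.34, 0.10 and 0.40. Of the other lists, the cell cycle list held 1 rise, TYMS by 0.29, and the STAT3 and cytokine list 2, IL6 and IL10, with 5 rises and 2 falls when adjusted over the list alone. Neither passed as a list (adjusted p = 0.354 and 0.541). In all, 102 genes passed, 85 higher and 17 lower (83.3% higher), and 96 with the slide as a random block, while within OCILY10 the count was 0 (1385 at unadjusted p under 0.05, limma) and within TMD8 0 (2868). The count was 0 without the TMD8 3 h or the TMD8 6 h array, 9 without OCILY10 6 h, 19 without OCILY10 3 h, 193 without OCILY10 24 h and 211 without TMD8 24 h. It was 0 with trend and robust eBayes (3086 at unadjusted p under 0.05) and with Agilent's processed signals (3011), 8 with scaling between arrays (5 higher, 3 lower), and 12066 with centring over the tested genes (5624 higher, 6442 lower).

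The difference between late and early times cancels a constant dye effect. The interferon-stimulated list was higher late by 0.75, with 33 members higher and none lower when adjusted over the list alone and 0 over all genes (adjusted p = 9.8e-34). The list's adjusted p = 0.389 with an estimated correlation, with a range of 1e-69 to 0.389 over the alternatives. With the slide as a fixed term, which leaves the estimate within OCILY10, the list difference was 1.03. Apoptosis genes (0.075, adjusted p = 0.0344, 2 higher alone) and myeloid markers (0.20, adjusted p = 0.0217, 1 higher alone) also passed as lists, each with adjusted p = 0.389 with an estimated correlation. Their ranges over the alternatives were 0.0225 to 0.55 and 9.3e-05 to 0.389. The myeloid difference rests partly on a mean of -0.20 on the OCILY10 3 h array (SD over 10 genes 0.75), where the median was 0.028. The medians on the other arrays were 0.0031 to 0.080 early and 0.0041 to 0.17 late. No single gene passed by limma (smallest adjusted p = 0.613; 1145 at unadjusted p under 0.05). The smallest p-values belonged to ISG20, an interferon-induced exonuclease gene at 0.67 (SE 0.081, adjusted p = 0.613), C12orf57 at 0.41 and CAPN2, a calpain gene, at 0.36, and to REEP2 at -0.45, the B-cell tetraspanin gene CD37 at -0.40 and DBN1 at -0.28 (adjusted p = 0.873 for these 5). With the slide as a fixed term 4 genes passed, all higher late within OCILY10 and singled out after their values were seen: HBD by 1.81, LGALS1 by 1.65, NEURL3 by 1.08 and a transcript without a gene symbol by 1.31. Without the TMD8 24 h array 86 genes passed, 77 higher and 9 lower, 33 of them members of the interferon list. The list mean was then 1.02, and its call held with an estimated correlation (adjusted p = 0.018). The array left out held the lowest late interferon mean, so its removal favours this call and gives no separate support.

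At single times, with 1 array per line, only 48 h gave genes past the threshold. At 48 h, 24 of 53 interferon-stimulated genes rose (48 when adjusted over the list alone, none lower) with a mean of 1.21, including IFI44L by 3.39 (SE 0.64, adjusted p = 0.0495), IFI44 by 2.80 and IFIT3 by 1.88 (SE 0.24, adjusted p = 0.038). The death genes TNFSF10, CASP4, TNFRSF10B and FAS rose by 0.53 to 0.92, IL6 rose by 0.76 and the endothelial adhesion gene PECAM1, a stromal list member, by 0.94. The falls included PTOV1 by 0.81, ADIRF by 0.78 and SEPTIN5 by 0.73 (SE 0.069, adjusted p = 0.0299). They also included 3 of 20 amino acid stress genes (2 higher and 6 lower when adjusted over the list alone): PHGDH, which starts serine synthesis, by 0.66, the amino acid transporter gene SLC7A5 by 0.43 and CEBPB by 0.41. That list passed at a mean of -0.14 (adjusted p = 0.00685, and 0.365 with an estimated correlation), but stood at 0.13 in OCILY10 and 0.16 in TMD8 under median centring. The cell cycle list passed at -0.14 (adjusted p = 2e-05, and 0.365 with an estimated correlation), with none past the threshold over all genes and 2 lower alone, and turned to 0.21 and 0.20 under median centring. Glycolysis and hypoxia genes passed at -0.18 (adjusted p = 0.00162, and 0.513 with an estimated correlation; 1 fall, 3 alone), with means of 0.038 in OCILY10 and -0.41 in TMD8, and 0.15 and -0.011 under median centring. Cholesterol synthesis genes passed at -0.11 (adjusted p = 0.0386, and 0.365 with an estimated correlation; none alone), and stood at 0.25 and 0.23 under median centring. The interferon list's adjusted p = 2.1e-23, and 0.475 with an estimated correlation. By fry, which tests a list against no change and not against other genes, these 5 lists had adjusted p = 0.0381, 0.0104, 0.201, 0.11 and 0.0355.

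**Figure D4:**
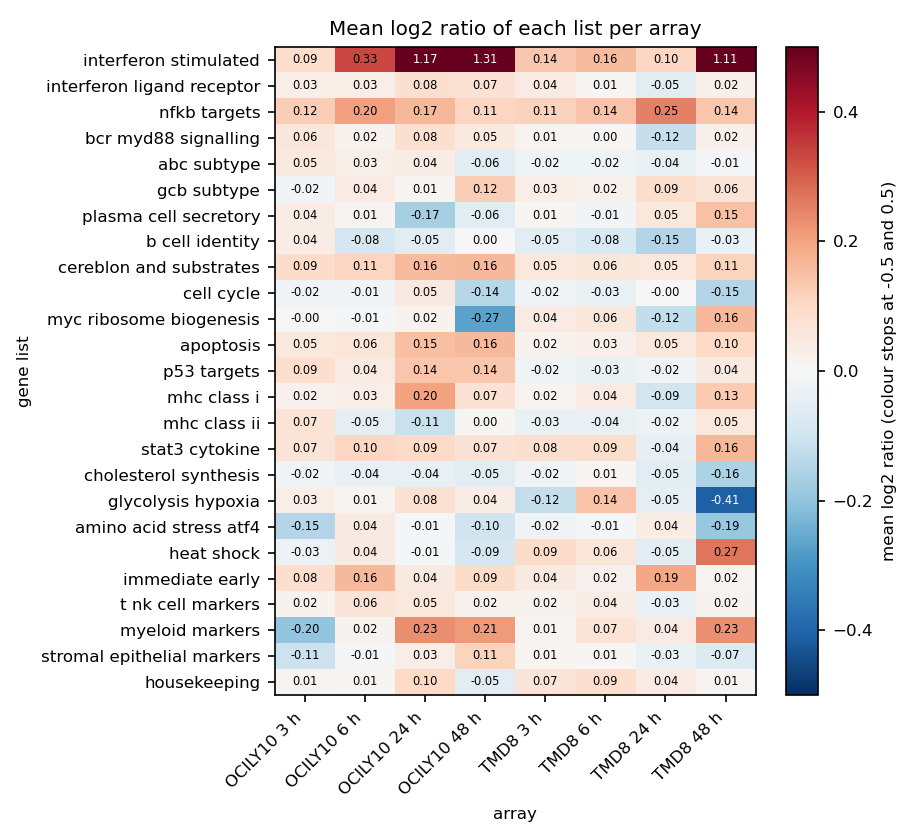
Mean log2 ratio of lenalidomide over DMSO of the 25 gene lists (vertical) on each of the 8 arrays (horizontal), with the mean printed in each cell and colour from blue (negative) to red (positive), stopping at -0.5 and 0.5. The interferon-stimulated list stood at 1.17 and 1.31 in OCILY10 at 24 and 48 h, and at 0.10 and 1.11 in TMD8.

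At 24 h the 3 genes of smallest p in each direction, none past the threshold (adjusted p = 0.133 each), were CD58 at 0.71, IL6 at 0.68, the metallothionein gene MT1A at 0.55, KLF2 at -0.76, the exon junction gene EIF4A3 at -0.53 and DBN1 at -0.51. The 24 h interferon list stood at 0.64 (11 higher alone; adjusted p = 2.8e-20, and 0.542 with an estimated correlation). NF-κB targets stood at 0.21 (9 higher and 1 lower alone; adjusted p = 3.7e-05, and 0.141 with an estimated correlation), and MHC class II genes at -0.067 (0 higher and 2 lower alone; adjusted p = 0.0494, and 0.445 with an estimated correlation), with 0.35 in TMD8 under median centring. At 6 h CD58 at 0.61, FAM241A at 0.55 and IL10 at 0.51 (adjusted p = 0.428 each) had the smallest p above 0, and KLF2 at -0.54, TBL2 at -0.48 and REPIN1 at -0.46 (adjusted p = 0.531 each) below it. The 6 h lists past the threshold were NF-κB targets at 0.17 (5 higher alone) and interferon-stimulated genes at 0.25 (none alone), each with adjusted p = 4.8e-06, and 0.0984 and 0.893 with an estimated correlation. At 3 h no list passed, and ABCA6 at 1.16, HSPA13 at 0.94, FAM241A at 0.55, TNRC6B at -0.50, TXNL4A at -0.34 and PFN1P2 at -0.30 had the smallest p (adjusted p = 0.447 each).

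At 48 h 543 genes passed, 384 higher and 159 lower (70.7% higher), 574 with the slide as a random block and 170 with the cell line as a block (135 higher, 35 lower). The counts by limma were 0 at 3, 6 and 24 h (2306, 1225 and 1976 at unadjusted p under 0.05). Without single arrays the 48 h count was 0 (OCILY10 3 h, OCILY10 6 h, TMD8 3 h or TMD8 6 h), 11 (OCILY10 48 h), 22 (TMD8 48 h) and 1850 (OCILY10 24 h or TMD8 24 h). It was 0 with median centring (8177 at unadjusted p under 0.05), scaling between arrays (1643), trend and robust eBayes (5635), Agilent's processed signals (2918) and the 3 and 6 h arrays as baseline (2109), and 1090 with centring over the tested genes (463 higher, 627 lower). Leaving out its own arrays gave 415 genes at 3 h (TMD8) and 10 (OCILY10), 45 at 6 h (OCILY10) and 1 (TMD8), and 504 at 24 h (OCILY10) and 88 (TMD8). Median centring gave 12959 genes at 3 h (10272 higher, 2687 lower), and centring over the tested genes 11041 (4183 higher, 6858 lower).

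Between the lines, the late response differed for 4 genes, all higher with the drug in OCILY10 at 24 and 48 h. HBD, the delta globin gene, stood at 2.09 and 2.19 in OCILY10 and at -0.035 and -0.057 in TMD8, a difference of -2.19 (SE 0.14, adjusted p = 0.00484). LGALS1, which encodes galectin-1, stood at 1.75 and 1.60 against 0.097 and 0.34 (difference -1.46, SE 0.11, adjusted p = 0.0135). NEURL3, a ubiquitin ligase gene, stood at 1.16 and 1.20 against 0.014 and 0.010 (difference -1.17, SE 0.071, adjusted p = 0.00484), and its difference was -4.25 with Agilent's processed signals. The remaining call was a transcript without a gene symbol at -1.59. HBD and NEURL3 had no value with the strict filter, so their signal was not well above background in both channels on every array. For these genes a signal too dim to measure in TMD8 is not separated from a lack of response. CTTNBP2 at 0.86 (adjusted p = 0.0614), IL3RA, an interleukin 3 receptor gene, at 0.95 and ACP3 at 0.90 (adjusted p = 0.0734 each) had the smallest p among genes higher in TMD8 and did not pass.

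As lists, interferon-stimulated genes were lower in TMD8 by a difference of -0.63, with 0 members past the threshold over all genes and 7 lower when adjusted over the list alone (adjusted p = 2.7e-09). Adjusted p = 0.699 with an estimated correlation, in a range of 8.9e-38 to 0.699 over the alternatives. Without the TMD8 24 h array the difference was -0.13 (adjusted p = 0.55), and without TMD8 48 h it was -1.15. Plasma cell and secretory genes were higher in TMD8 by 0.20 (adjusted p = 2.4e-05, and 0.392 with an estimated correlation, range 2.5e-06 to 0.392; 2 higher alone). MYC and ribosome biogenesis genes were higher by 0.15 (adjusted p = 0.00298, and 0.699 with an estimated correlation; none alone), with -0.014 under scaling between arrays, 0.0027 without the TMD8 48 h array and 0.0030 without OCILY10 48 h. Glycolysis and hypoxia genes differed by -0.30 (adjusted p = 0.00439, and 0.699 with an estimated correlation; 1 higher and 4 lower alone), with 0.058 under median centring, -0.098 without the TMD8 48 h array and -0.10 with the strict filter. Heat shock genes were higher by 0.16 (adjusted p = 0.0149, and 0.699 with an estimated correlation; none alone), with -0.0050 without the TMD8 48 h array. The adjusted p of these 3 had ranges of 2.5e-06 to 0.699, 2.5e-06 to 0.699 and 2.6e-06 to 0.963 over the alternatives. Line and slide cannot be told apart, since OCILY10 lay on slide 1 and the late TMD8 arrays on slide 2. HBD, LGALS1 and NEURL3 also rose from early to late within slide 1, by 1.81, 1.65 and 1.08, which a constant effect of that slide cannot give. An effect of slide 2 on their late TMD8 values is not separated. The count by limma was 105 without OCILY10 24 h, 37 without TMD8 48 h and 13 without TMD8 24 h (7 higher, 6 lower). It was 11 with median centring (4 higher, 7 lower), 1 with the strict filter and 0 with trend and robust eBayes (2460 at unadjusted p under 0.05), scaling (1320), centring over the tested genes (922), Agilent's processed signals or the value table (2791 each).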

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

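The tests of the dye effect in genes picked on one line, of an array-wide component and of a property of single probes were set before their results were seen. The differences between the lines and between late and early times were planned before the data were seen, and all other tests here were chosen only after the result was seen.

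The interferon-stimulated list stood at 0.10 on the TMD8 24 h array, far from the other late arrays at 1.11 to 1.31. That array had the lowest median signal in Cy3 (168) and Cy5 (195) and the lowest share of Cy5 spots well above background (56.5%). It also had the most non-uniform spots (46 in Cy3, 40 in Cy5). On it 164 genes lay below -1 and 19 above 1, against 6 and 70 at TMD8 48 h and 254 and 37 at OCILY10 3 h. Whether this quality bears on the interferon value was not tested. A swap with the TMD8 3 or 6 h array is argued against, since neither held the missing response (the higher list mean was 0.158). Whether an array-wide component hid it could not be decided. The lowest mean of 10000 random lists of like brightness was -0.18, against a missing response of 1.00. Loess had already centred each array near 0 across brightness, so random lists had little room to move. RNA of the other line is argued against, since the log2 of Agilent's processed signals correlated at 0.950 to 0.981 (Cy5) and 0.941 to 0.975 (Cy3) with the other TMD8 arrays. With the OCILY10 arrays they correlated at 0.922 to 0.928 and 0.904 to 0.919. Another wrong sample or a culture without active drug stays open. Without the interferon list, the change from 3 and 6 h correlated across genes with that on OCILY10 48 h at 0.181, against 0.157 for TMD8 48 h. The reference of 0.315, the higher correlation between the lines at 3 or 6 h, was for ratios and not for changes. Genes are not independent replicates. A slower response in TMD8 may also account for the value, and it was not tested.

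Genes past the threshold at 24 and 48 h mostly lay the same way at 3 and 6 h: 95.0% had the same sign early, against 70.4% of the genes that did not pass, with a median early over late ratio of 0.512. The 86 ribosomal protein genes, grouped after their values were seen, hold 46 rises and 1 fall. Their mean changed by 0.0053 from early to late (SD of the 8 array means 0.093). A gene-specific dye effect could give this, and so could a change complete by 3 h. By array these genes had means of 0.18, 0.21, 0.21 and 0.31 in OCILY10 and 0.37, 0.37, 0.41 and 0.21 in TMD8 at 3, 6, 24 and 48 h. Their medians on the 8 arrays, relative to all tested genes, were 0.14 to 0.43, against 0.029 to 0.15 with Agilent's processed signals, where the mean on the OCILY10 3 h array turned to -0.017, 0.12 to 0.96 under scaling between arrays and 0.72 or more under median centring. For the interferon list a dye effect is argued against, since its late minus early difference was 0.744 (SE 0.281). For other genes picked on one line, the early shift on the other line was 0.694 of the late shift whichever line was picked (845 and 520 genes), so a dye effect and an early drug effect cannot be told apart without swapped dyes.

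On the 24 h arrays the changes from 3 and 6 h went opposite ways in the lines, with a correlation across genes of -0.35 without the interferon list, against 0.16 at 48 h (genes are not independent replicates). Reversed channels are argued against on the OCILY10 24 h array, where the interferon list mean was 1.17. On the TMD8 24 h array the mean of 0.105 cannot decide this, since that array held little interferon response to reverse. A property of single probes stays open: the 2 brightest probes of 5633 genes correlated at 0.368 for the 24 h difference between the lines, against 0.481 for the 48 h mean. A biological difference between the lines at 24 h was not tested and could remain.

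Of 50 groups of 4 arrays, 5 held an array far from the others, and chance alone gives about 1 in 20 groups. Besides the interferon list, MHC class II genes stood at 0.070 on the OCILY10 3 h array (others -0.049 to -0.034). Cholesterol synthesis genes stood at -0.16 on the TMD8 48 h array (others -0.054 to -0.038). Myeloid markers stood at 0.042 on the TMD8 24 h array (others 0.21 to 0.23), and stromal and epithelial markers at -0.11 on the OCILY10 3 h array (others -0.0098 to 0.0095).

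The late response differed between the lines, as TMD8 minus OCILY10, for HBD (-2.19), a transcript without a gene symbol (-1.59), LGALS1 (-1.46) and NEURL3 (-1.17). Lists that differed by camera were interferon-stimulated genes (-0.63), plasma cell and secretory genes (0.20), MYC and ribosome biogenesis genes (0.15), glycolysis and hypoxia genes (-0.30) and heat shock genes (0.16). All 5 calls were lost with an estimated correlation (adjusted p = 0.392 to 0.699), and the interferon difference was -0.13 (adjusted p = 0.55) without the TMD8 24 h array. For genes that differ between late and early times, the real grouping gave 0 calls and the highest of the other splits of the 8 arrays also gave 0. All 35 of 35 splits thus gave a count as large, an outcome that a real count of 0 fixes, so these splits cannot show whether chance can be excluded.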

How the results depend on the processing

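The 3 and 6 h baseline and median centring over the tested genes were tests chosen only after the data were seen, and so was giving median-centred values relative to the median of all tested genes, because raw values turned many signs. Of 264 counts under an alternative, 163 stayed within 1.5 times the main count. Of 694 list values 573 kept direction and side, 57 lost the call, 24 gained it, 36 moved and 4 turned. Of 3670 named-gene values 2379 kept both, 1219 lost the call, 27 gained it, 17 moved and 28 turned. Of 129 named-gene calls, 109 held with an offset of 0, 52 with Agilent's processed signals, 1 with scaling and 0 with trend and robust eBayes. With the slide block 126 of 126 held, but its correlations of 0.00277 by phase and 0.0537 by time left the fit close to the main one. That block thus cannot exclude a slide effect. The 4 arrays per phase, with signal over background in 41.4% to 62.8% of Cy3 spots, limit what weak changes can show. No paired analysis by replicate number was possible because each line and time had 1 array, and late and early arrays were paired only by line, as a block. Of 64 named genes with several probes, 11 had probes with late means of both signs, and in 14 more, of 1 sign, the largest was over 3 times the smallest. The smallest late means of these were IFIT2 (0.29), KLF2 (-0.12), RPL18 (0.11), TNRC6B (-0.036), REPIN1 (-0.040), ACP3 (-0.038), FAM241A (0.093), JAK1 (-0.11), SOD2 (0.0043), BCL2 (0.059), SLC7A11 (0.041), CEBPB (-0.067), KLF6 (0.078) and CDKN1A (0.074). The slide as a block was not run for the line difference, which it confounds. The cause was not tested for any change listed here, except that fewer arrays or genes entered where arrays were left out or a strict filter was used.

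Median centring gave 3801 genes at 24 and 48 h, 10331 at 3 and 6 h, 12959 at 3 h, 0 at 48 h (8177 at unadjusted p under 0.05, limma) and 11 between the lines. It gave 19 lists late, 15 early and 6 late minus early. This setting leaves in any dye trend with brightness, and whether such a trend made the turns below was not tested. Median centring turned the cell cycle list late (0.26) and the glycolysis and hypoxia list between the lines (0.058). Among genes at 24 and 48 h it turned ADAM8 (0.018), IFNGR2 (0.083), RELB (0.31), SPIB (0.20), RAB29 (0.051), TCF3 (0.13), MS4A1 (0.045), CD72 (0.13), UBE2C (0.29), LDHA (0.25), BTG2 (0.18), CD74 (0.049), BCL3 (0.26), MVK (0.17), SREBF2 (0.069), SLC7A11 (-0.018), TRIB3 (0.093), SLC3A2 (0.098) and VIM (0.26). It turned REPIN1 (0.25), TMBIM6 (0.34), TERT (0.10) and TXNL4A (0.40) early, and IFNGR2 (0.032), TCF3 (0.011), LDHA (0.15) and CD74 (0.050) at 48 h. Centring over the tested genes gave 3539 late, 12066 early, 11041 at 3 h, 1090 at 48 h and 0 between the lines (922 at unadjusted p under 0.05). Scaling between arrays gave 15 genes late, 8 early, 0 at 48 h (1643 at unadjusted p under 0.05) and 0 between the lines (1320). With it, 1 list passed early and 3 between the lines, NF-κB targets stood at 0.21 late and 0.20 early without passing (adjusted p = 0.0833 and 0.0676, ranges 1.4e-05 to 0.446 and 1.5e-05 to 0.293), and MYC and ribosome biogenesis turned to -0.014 between the lines.

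With only the arrays of a comparison, 0 genes passed late (4051 at unadjusted p under 0.05) and 1640 early. Trend and robust eBayes gave 0 late (6420), 0 early (3086), 0 at 48 h (5635) and 0 between the lines (2460). A minimum of 1.5-fold gave 138 late, 6 early and 125 at 48 h. OCILY10 alone gave 127 late and 0 early (1385), and TMD8 alone 0 late (4102) and 0 early (2868). Agilent's processed signals gave 0 early (3011), 0 at 48 h (2918), 0 between the lines (2791) and 1 list late minus early, and the value table gave 0 early (3011), 0 at 48 h (2916), 0 between the lines (2791) and 1 list. An offset of 0 gave 15 early and 1464 at 48 h. The strict filter gave 164 early, 223 at 48 h, 1 between the lines and 1 list early, where the interferon list at 0.18 lost its call (adjusted p = 0.0596, range 2.4e-06 to 0.97). The mean of the probes gave 56 early and turned NPM1 to -0.043. The slide block gave 4 genes and 5 lists late minus early, the line block 170 genes at 48 h and 5 lists late, and the 3 and 6 h baseline 0 at 48 h (2109). Non-uniform spots kept gave 1 list early, with the interferon list at 0.18 (adjusted p = 0.0565), and 7 lists late minus early.

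With an estimated correlation 0 lists passed late, early, late minus early or between the lines, where interferon stood at 0.92, 0.18, 0.75 and -0.63 and NF-κB targets at 0.17 late and 0.15 early. Fry gave 7 lists late, 0 late minus early and 0 between the lines, and left interferon at 0.18 early, 0.75 late minus early and -0.63 between the lines without a call.

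Leaving out each array in turn, with lone arrays assumed to vary like the others, gave 392 to 2833 genes late, 0 to 211 early, 0 to 86 late minus early, 0 to 415 at 3 h, 0 to 45 at 6 h, 0 to 504 at 24 h, 0 to 1850 at 48 h and 3 to 105 between the lines. The lists passing were 3 to 5 late, 1 to 2 early, 2 to 8 late minus early and 3 to 6 between the lines. The interferon mean was 0.80 to 1.19 late, 0.13 to 0.21 early, 0.62 to 1.02 late minus early and -1.15 to -0.13 between the lines, and NF-κB targets were 0.14 to 0.19 late and 0.13 to 0.16 early. The heat shock difference between the lines was -0.0050 without TMD8 48 h, where it turned, to 0.32 without TMD8 24 h.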

Other observations

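The groups in this part were singled out after their values were seen. Metallothionein genes, which encode small metal-binding proteins, had medians above 0 on every array, also under each of the 3 scalings tried. Over 10 genes these were 0.14, 0.43, 0.98 and 0.32 in OCILY10 and 0.22, 0.33, 0.56 and 0.32 in TMD8 at 3, 6, 24 and 48 h. Their sizes and order in time moved with the setting: OCILY10 3 h stood at 0.88 under median centring, and TMD8 24 h at 1.25 under scaling between arrays. On the OCILY10 24 h array MT1B, MT1E, MT1G, MT1H, MT1L and MT1X stood at 0.95 to 1.05, and MT1A, MT1F and MT1M at 0.36 to 0.60. Whether their probes read separate transcripts was not tested, and a gene-specific dye effect is not separated from values above 0. The gene MT2A stood at 1.18 on the OCILY10 and 0.70 on the TMD8 24 h array, and rose at 24 and 48 h by 0.68 (SE 0.12, adjusted p = 0.0153).

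At 48 h metabolic and stress genes gave different values in the 2 lines, a difference not tested at 48 h alone. In TMD8 the median of 20 glycolysis and hypoxia genes was -0.33 (none above 0; 0.11 under median centring), with ENO2 at -1.12, the adrenomedullin gene ADM at -1.08 and the carbonic anhydrase gene CA9 at -1.05, while in OCILY10 it was 0.024 (-0.034 with Agilent's processed signals and -0.00080 under scaling between arrays) and ADM stood at 1.02. All 12 heat shock genes were above 0 in TMD8 (median 0.23), against 4 of 12 in OCILY10 (median -0.076; 0.42 under median centring). Of 25 MYC and ribosome biogenesis genes, 21 were above 0 in TMD8 (median 0.18) and 4 in OCILY10 (median -0.19; 0.26 under median centring), where the polyamine gene SRM stood at -0.94 and the pyrimidine gene CAD at -0.78. MIR155HG, the host transcript of miR-155, stood at -0.85 and -1.10 in OCILY10 at 24 and 48 h and at 0.54 and -0.063 in TMD8 (adjusted p = 0.108 for the late difference). The T-cell attracting chemokine gene CXCL9 stood at 1.47 and 1.93 in OCILY10 and at 0.031 and 0.30 in TMD8 (adjusted p = 0.0734), and the chemokine gene CCL3 at 1.06 on the TMD8 24 h array against 0.074 in OCILY10 (adjusted p = 0.214). None of these 3 single-gene differences passed, and each single value comes from 1 array.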
